A study of Mesocricetus auratus with 3 samples.

How the data were processed

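RNA from the testes of pinealectomised and control Syrian hamsters was compared on 3 two-colour spotted arrays. Per the labels, each array is a biological replicate and carries 1 pinealectomised and 1 control RNA. On replicates 1 and 2 the pinealectomised RNA was labelled with Cy5 and the control RNA with Cy3, and on replicate 3 the dyes were exchanged. The labelling text names Cy3 for both channels, so the dye of each RNA was taken from the label field of its channel. Per the labels' protocols, total RNA was extracted with Trizol and copied from an oligo-dT primer into fluorescent cDNA. How many animals stand behind each RNA, their day length, their age and the time since surgery are not given in the labels.

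The authors deposited 1 scan table per dye and array, holding for each spot the intensity of the spot and of its local background, neither subtracted nor normalized. Per the file headers, the spots were segmented automatically by the quantification software (header version 4.1), with a background ring 3 pixels wide at a distance of 3 pixels. Each array has 48 blocks and 12288 spots, which are 6144 clones printed as 2 neighbouring spots each. The deposited tables also carry a spot mark, another code from 0 to 3 whose meaning is not given in the sources used here. Mark 2 was given to 2618 spots of replicate 1, to 7472 spots of replicate 2 and to 0 spots of replicate 3, and on replicates 1 and 2 these spots had a median Cy5 signal of 0.486 and 0.751 background SDs above the local background. The deposited value table of the series holds log2 ratios. It lists 15247 clones, of which 9103 are not in the scan tables and have no value. All 4829, 2382 and 5906 of its values for replicates 1, 2 and 3 equalled, within 0.001, the log2 of the mean over a clone's 2 spots of the background-subtracted pinealectomised over control signal, with the dyes exchanged on replicate 3 as in the labels. That table is therefore neither centred nor corrected for brightness, and its columns had medians of -0.50, 0.15 and -0.03.

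Ratios were computed from the scan tables with limma 3.58.1 in R 4.3.3. Mean spot and mean background signals were corrected with normexp and an offset of 50, and normalized within each array by global loess. No spot is named as a control. Spots with a mark other than 0 in either dye were given weight 0 in the loess and left out. The log2 ratios of a clone's remaining spots were averaged, and the sign was turned on replicate 3 so that positive values are higher in pinealectomised testes. A clone was tested if it had an unmarked spot on every array and, on every array, a signal over the local background by more than 2 background SDs in at least 1 RNA. This left 2559 clones. The offset draws the ratios of dim clones toward 0, so the fold changes of dim clones are understated.

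The mean log2 ratio of each clone was tested against 0 with lmFit and eBayes (2 residual degrees of freedom, 7.06 after moderation), two-sided, with Benjamini-Hochberg adjustment at 0.05. Confidence intervals are 95% intervals of that fit. Arrays give no counts, so precision is limited by the number of arrays. The p-values rest on a clone's spread between these 3 pairs, moderated toward the spread of all clones. That moderation supplies 5.06 of the 7.06 degrees of freedom, so the p-values also depend on the variance prior. Exchanging the signs of whole arrays gives 4 distinct assignments, so an exact sign-flip test of a single clone cannot go below a two-sided p of 0.25. The steps were tested on simulated spots of this comparison, with 200 clones changed by known folds. Of 2543 simulated clones tested, the fit recovered 18% of those changed by 1.5-fold, 78% at 2-fold, 80% at 3-fold and 94% at 4-fold, and 10 of its 146 calls (6.8%) were of unchanged clones. The simulation gave a clone the same change and the same spread on all 3 arrays. It also drew the spread without regard to brightness and kept clones independent. The real arrays differ in spread, so these rates show that the steps run as intended and need not hold for the real data.

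The files name the spots by clone ID only. None of the 6144 IDs matched a gene ID, locus tag, symbol, synonym or accession in the hamster gene table used here (assembly BCM_Maur_2.0), so 0 of the 26 gene lists fixed before the data were examined could be tested, and no gene, chromosome or annotation is given for a clone. The IDs name a source plate and well, so the lack of a match says nothing about the clones. The species from which the clones were made was not established here, nor was its effect on the signals. The rule for naming was also fixed then: the clones with the largest mean change among those past the threshold with all 3 arrays the same way. Because the IDs are not paired with genes, the first 2 higher and the first 2 lower clones of that rule are named. Alternatives covered the background correction, the normalization within and between arrays, the pixel statistic, the filters on dim and marked spots, a dye term, array weights, the variance prior, the authors' value table, a model without the array as a pair, and leaving out each array. Figures were drawn with matplotlib 3.10.9.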

Results

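Gene expression was measured in the testes of pinealectomised Syrian hamsters, in which the pineal gland, the main source of circulating melatonin, had been removed, and in the testes of control animals. There were 3 arrays, each with 1 RNA of either kind, and the third had the dyes exchanged. The median spot was 3.4 times its local background in Cy5 and 2.62 times in Cy3 on replicate 1. On replicate 3 these ratios were 2.92 and 2.26. Replicate 2 was the dimmest, at 1.36 and 1.35. Of the 6144 clones printed, 4896, 2584 and 6117 had an unmarked spot on replicates 1, 2 and 3, and 2559 met the criteria for testing on all 3. The brightest spot on any array had a mean signal of 57126. The duplicate spots of a clone gave log2 ratios that differed by a median of 0.049 on replicate 1, 0.137 on replicate 2 and 0.078 on replicate 3.

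The first question was which transcripts differ in abundance between pinealectomised and control testes. Of the 2559 clones tested, 166 (6.49%) differed, of which 63 were higher and 103 were lower in pinealectomised testes (limma, Benjamini-Hochberg adjusted p under 0.05). All 166 moved the same way on all 3 arrays, which a test of the mean of these arrays favours. The 63 higher clones rose by a median of 1.12 on the log2 scale, or 2.17-fold, with a range from 0.68 to 2.90, and 41 of them changed by more than 2-fold. The 103 lower clones had a median change of 0.94 in size, or 1.92-fold, with a range from 0.69 to 1.82, and 42 of them changed by more than 2-fold. The standard error of the mean log2 ratio had a median of 0.17 over the 166 clones (n = 3 arrays). Mean changes beyond 4-fold were seen in 7 higher clones and in 0 lower clones, but in 5 and 1 with median centring, 9 and 2 without replicate 3, 4 and 3 in the authors' value table and 7 and 3 in its centred form. Most clones changed little, and 2215 of the 2559 (86.6%) had a mean change under 1.5-fold in either direction.

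**Figure D1:**
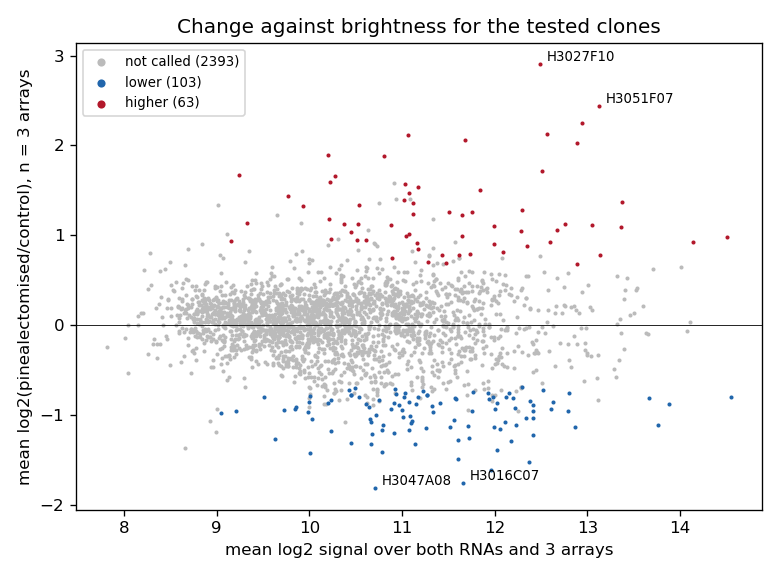
The mean log2 ratio of pinealectomised over control testes (vertical axis, n = 3 arrays) is plotted against the mean log2 signal (horizontal axis) for the 2559 tested clones, 1 point per clone, with the 63 higher clones in red, the 103 lower clones in blue and the others in grey. The 7 clones beyond 4-fold (2 on the vertical axis) all lie on the higher side with loess.

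The number of clones past the threshold depended on the dimmest array and on the model. Without replicate 2 the same fit called 429 of the same 2559 clones, 178 higher and 251 lower, and these included all 166. Of the 166, 85 stayed past the threshold with no background correction and 96 with a brightness trend and a robust variance prior. Without replicate 1, 121 of them stayed, and without replicate 3, 127. The number called ranged from 85 to 470 over the other paired alternatives, and it was 0 in a model that did not pair the RNAs of an array. Lower clones made up 62% of the calls after loess and 73% after median centring alone (57 higher and 154 lower). In the authors' value table, which is not centred and has a median change of -0.15 over its clones against 0.05 after loess, they made up 80.9% (51 higher and 216 lower), and 72% once its columns were centred. With a brightness trend and a robust variance prior they made up 91.3% (9 higher and 95 lower), and without replicate 3 they made up 54.7% (82 higher and 99 lower). Lower clones were the majority in each of these fits, but the size of the majority depended on the scaling, the variance prior and the arrays included. At an unadjusted p under 0.05 the fit gave 604 clones, 283 higher and 321 lower, where chance alone would give about 128.

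Clone H3027F10 showed the largest rise. It was 7.49-fold higher in pinealectomised testes, with a log2 ratio of 2.90 ± 0.59 (SD, n = 3) and a 95% confidence interval from 2.36 to 3.45 (limma, Benjamini-Hochberg adjusted p = 0.0037). Its background-subtracted signal was 42421 in the pinealectomised and 4140 in the control RNA on replicate 1, and 7525 and 1470 on the dye-swapped replicate 3. Clone H3051F07 was 5.41-fold higher, at 2.44 ± 0.51 (SD, n = 3), with an interval from 1.93 to 2.94 (limma adjusted p = 0.0052). The largest fall in this fit was that of clone H3047A08, which was 3.53-fold lower, at -1.82 ± 0.33 (SD, n = 3), with an interval from -2.23 to -1.41 (limma adjusted p = 0.0068). Clone H3016C07 was 3.38-fold lower, at -1.76 ± 0.52 (SD, n = 3), with an interval from -2.27 to -1.25 (limma adjusted p = 0.0105). H3016C07 fell further than H3047A08 with no background correction, without replicate 1 and without replicate 3. All 4 clones were above background in both RNAs on all 3 arrays. The genes these clones represent are not given here.

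**Figure D2:**
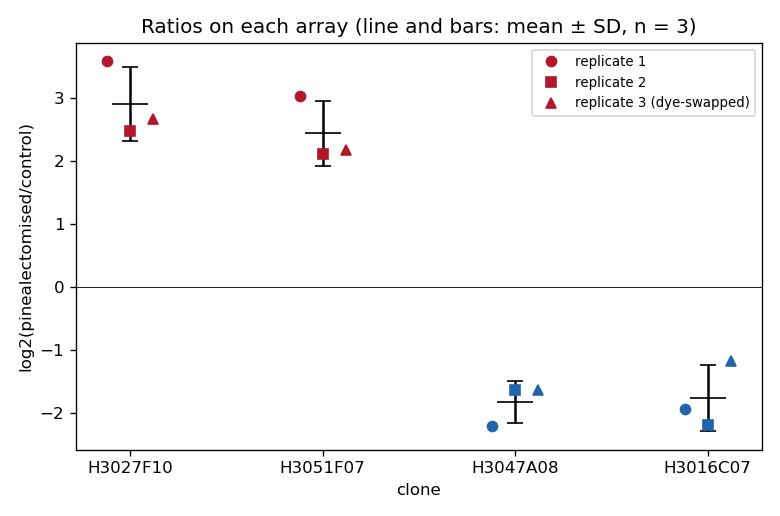
The log2 ratio of pinealectomised over control testes (vertical axis) is shown for the 2 clones with the largest rise and the 2 with the largest fall (horizontal axis), with 1 symbol per array and the mean ± SD of the 3 arrays in black. The dye-swapped replicate 3 lies on the same side of 0 as the other arrays for each of the 4 clones, which the rule for naming required.

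None of the 2559 tested clones, the 166 changed ones included, was below background on all 3 arrays in either RNA. In 21 of the 166 at least 1 RNA was not well above background on at least 1 array. This was the pinealectomised RNA in 16 clones and the control RNA in 6. The ratio of such an array, which enters the mean, is only a bound.

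The second question was whether the 3 pairs of testes changed alike. Across the 2559 clones, which are not independent replicates, the log2 ratios of replicates 1 and 3 correlated with a Pearson r of 0.75 (Spearman 0.64). Replicate 2 was less close to the others, with r = 0.44 against replicate 1 and r = 0.43 against replicate 3. These correlations differed with brightness: in the brightest tercile of clones replicate 2 correlated at 0.637 with replicate 1 and 0.712 with replicate 3, and in the dimmest at 0.211 and -0.059. Replicates 1 and 3 correlated at 0.858 in the brightest and 0.392 in the dimmest tercile. The sign of the ratio was the same on all 3 arrays for 1277 clones (49.9%), where independent signs would give 25%. The spread of the ratios also differed between arrays, with an SD across clones of 0.64 on replicate 1, 0.51 on replicate 2 and 0.40 on replicate 3.

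**Figure D3:**
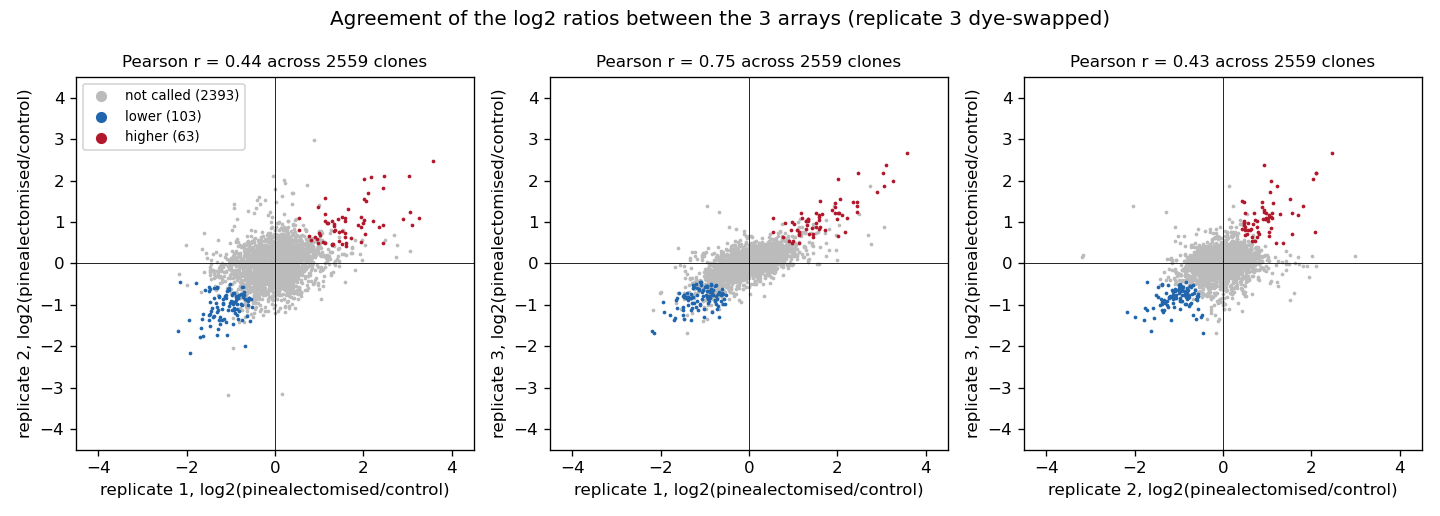
Each panel plots the log2 ratio of pinealectomised over control testes on one array against that on another, 1 point per tested clone, with higher clones in red, lower clones in blue and the others in grey. The closest pair is replicates 1 and 3, which carry opposite dyes (r = 0.75 across 2559 clones). The changed clones lie in the 2 quadrants where both arrays move the same way, which their selection on the mean of the arrays favours.

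The third question, raised by the exchanged dyes, was how far the ratios differed between the 2 dye orientations. Since 1 array alone has the exchanged orientation, the dye term also holds whatever else set replicate 3 apart, and the dye and that array cannot be told apart. With a dye term in the model, 1 clone passed the threshold for the dye (limma, Benjamini-Hochberg; 25 at an unadjusted p under 0.05), and 196 passed for pinealectomy (83 higher and 113 lower). The dye term had an SD of 0.17 across clones and the pinealectomy term an SD of 0.41. That model leaves 1 residual degree of freedom per clone before moderation. The 25 clones are fewer than the about 128 that chance alone would give, so the dye test was conservative. Its 1 call does not show that dye effects were absent.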

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

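The direction of the 166 changes held in every alternative in which a clone could be fitted: none of them changed sign. The alternatives reuse the same arrays on which the 166 were chosen, so they are not independent evidence of direction. The 4 named clones stayed past the threshold in 72 of 76 alternative fits, with log2 ratios from 2.57 to 3.21 for H3027F10, 2.03 to 2.60 for H3051F07, -2.14 to -1.33 for H3047A08 and -2.05 to -1.36 for H3016C07, and the other 4 fits were those of the model without pairing. The number of clones was less stable. It was 85 (31 higher, 54 lower) with no background correction, 470 (193 and 277) with array weights, which weighted replicates 1, 2 and 3 by 0.66, 0.48 and 3.18, and 104 (9 higher, 95 lower) with a brightness trend and a robust variance prior. It was 267 (51 and 216) in the authors' uncentred value table and 244 (84 and 160) with the arrays scaled to one spread. The model with no replicate block treats each channel as its own sample and includes a dye term. It was fitted after the average signals of the arrays were set to one distribution. A clone's remaining brightness differences between arrays then enter the residual. It called 0 clones (limma; 5 at an unadjusted p under 0.05), 0 higher and 0 lower. Leaving out 1 array gave 124 to 429 clones, 46 to 178 higher and 78 to 251 lower, the highest of each without replicate 2. These fits kept the 2559 clones that met the criteria on all 3 arrays, so the array left out still shaped which clones were tested. The lowest correlation between 2 arrays was 0.429, and it was 0.289 with no background correction, 0.363 with median centring, 0.362 with marked spots kept, 0.363 with only marks 1 and 3 left out, 0.365 in the authors' value table and in its centred form, and from 0.429 to 0.749 with an array left out. The number of clones past the threshold for the dye was 1, and it was 3 with plain background subtraction or arrays scaled to one spread, 2 in the authors' value table, and 0 with no background correction, median centring, print-tip loess, median pixel signals, the filter on both RNAs, marked spots kept or only marks 1 and 3 left out. The cause of these differences between settings was not tested. The fit with only marks 1 and 3 left out and the centred value table were chosen after seeing the data, as was the test that turns whole arrays. With only marks 1 and 3 left out, 3124 clones were tested and 168 called, 147 of them among the 166. The gene list alternatives gave no value because no clone could be named. Turning the sign of any 1 array gave 0 clones against the real 166, so 1 of the 4 assignments gave as many, which are too few for a share under 0.05. Signal over background limits replicate 2, on which 2584 of the 6144 clones had an unmarked spot.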

Other observations

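The tests of the pins by print-tip loess calls, of carry-over, of the 2-fold ratio, of the 40 largest changes and of the amplitude in bright clones had bounds set before their results were seen. The dye test, the share of change left by print-tip loess, the plate test, the split by kind of neighbour, the removal of the dye variance and the counts by brightness and beyond 4-fold had none.

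Changed clones were mostly bright. Of the 166, 121 lay in the brightest tercile of the 2559 tested clones (47 higher, 74 lower; 14.2% of that tercile), 36 in the middle (12 higher, 24 lower) and 9 in the dimmest (4 higher, 5 lower). The offset draws the ratios of dim clones toward 0, and the arrays correlated less in the dimmest tercile, so a given change was less likely to be called there. The 166 were also unevenly spread over the 60 source plates that the clone IDs name (chi-square 86.5, permutation p = 0.0049, 10000 permutations). The permutations here and below moved calls regardless of brightness. Whether plates of uneven brightness gave this spread was not tested. Clones in consecutive wells of a plate row tended to change together. Of 1299 such pairs, 14 were called the same way (12 both lower, 2 both higher), against a mean of 2.85 and a highest of 10 over 10000 permutations (permutation p = 1e-04, the smallest they can give; 5e-04 after Benjamini-Hochberg adjustment over 5 kinds of neighbour). For the next well along a plate column the count was 4 of 1119 pairs (mean 2.44, permutation p = 0.229), and for the next clone along a spot row of the array it was 5 of 1242 (mean 2.74, permutation p = 0.139). These differences between kinds of neighbour were not themselves tested.

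Technical sources of the 166 changes were weighed first. A dye bias would turn the sign of the dye-swapped array, and its turned ratios correlated with both other arrays at 0.429 or above, which argues against the dye as the whole source. In the dimmest tercile, which held 9 of the 166, it correlated at 0.392 with replicate 1 and -0.059 with replicate 2. With 2 arrays in one orientation and 1 in the other, part of a dye effect stays in the mean, so a share for single clones stays open. Print-tip loess left 91.5% of the called clones' median change and turned no sign, which argues against print pins as the whole source. That measure had no bound set beforehand. By the measure that had, 71.7% of the clones stayed past the threshold, between the bounds for and against print pins. A share of pin effects therefore stays open for any of the clones. Carry-over between neighbouring wells also stays open: 19.3% of the called clones had a neighbouring well called the same way, between the bounds set beforehand for and against it. These clones made 18 pairs, against a mean of 5.29 and a highest of 16 over 10000 permutations (permutation p = 1e-04). Chance would thus give part of that share, but no permutation reached 18 pairs. Clones of the same or related genes placed in consecutive wells would look alike without gene names. A difference made by pinealectomy, in the cells or in the mix of cell types of the testis, was not tested apart from other differences between the animals.

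The largest changes were mostly rises, with 28 higher and 12 lower clones among the 40 largest. Without replicate 1 the 40 largest were 19 higher and 21 lower, a ratio of 0.9, so the excess among the 40 may come from replicate 1. Beyond 4-fold there were still 4 higher and 0 lower clones without it, too few to decide, and 4 higher and 3 lower in the authors' value table. The higher-to-lower ratio of clones beyond 2-fold, at 51 to 46, was 0.67 with median centring (47 to 70) and went the other way with print-tip loess (44 to 33), and the counts were 35 to 118 in the authors' value table and 46 to 76 in its centred form. The main ratio lay under the bound set beforehand for this test, so the part played by normalization stays open.

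Changes were wider on replicate 1. From the covariances between arrays, its amplitude was 1.64 times that of replicate 3 (bootstrap interval over clones 1.51 to 1.79) and 2.19 times that of replicate 2 (1.99 to 2.43), and in the brightest tercile 1.356 times (1.28 to 1.44) and 1.78 times (1.62 to 1.97). In the dimmest tercile the covariances gave no usable ratio to replicate 3 (bootstrap interval -65.1 to 71.8). If background compressed the ratios of the dimmer arrays, the gap should close in bright clones. It narrowed there against both arrays, but against replicate 3 it stayed above the bound set beforehand. That bound overlooked that replicates 1 and 2 share a dye orientation: a dye effect, if there was one, would raise the ratio to replicate 3. The variance of the dye term, which also holds noise and amplitude differences, was taken out as the most that a dye effect could hold. The ratio to replicate 3 was then 0.967 over all clones and 1.14 in the brightest tercile, and the ratio to replicate 2 was 1.88 and 1.71. Background compression, a dye effect, a larger response in the animals of replicate 1 and a difference in labelling or hybridisation all stay open.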
